A study of Mus musculus with 9 samples.

How the data were processed

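Total RNA of whole lung from 9 C57BL/6 mice, 3 in each of 3 groups, had been hybridised to Affymetrix arrays 24 h after instillation. Per the labels, biotin-labelled sense-strand DNA was made from 200 ng of RNA, and the authors computed log2 signals by RMA in Affymetrix Expression Console 1.1, a procedure that corrects background, normalises between arrays and summarises probes. The deposited table held log2 values with 2 decimals. That the unit is log2 was checked on the range of the values. The probe set definition and annotation version are not given in the sources used here, so no genome positions are given.

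The table had 21212 entries. Entries are named by NCBI Gene numbers, and 18786 carried exactly 1 gene symbol. They held 18784 genes, 18453 of them protein-coding, and a gene with more than 1 entry was represented by its brightest. The 2420 entries without a symbol and 6 with several were left out of the gene tests and are counted among the closing observations. The groups were taken from the sample titles. Replicate numbers 1 to 3 did not pair the arrays: of 9 pairs of equal number, 1 had a residual correlation over 0.1, and the own number was the best partner in 3.

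Each gene was fitted with limma 3.58.1 (R 4.3.3) on all 9 arrays with a mean per group and moderated variances (residual df 6, prior df 3.58). The contrasts were infected minus vehicle, anti-LIF minus control IgG in infected mice, and anti-LIF infected minus vehicle. P-values are 2-sided, and the Benjamini-Hochberg threshold was 0.05 over all genes tested in each contrast. Depth in the sense of read counts does not apply to arrays, whose number limits the precision. The p-values measure spread between these mice, and no batch or scan date is given in the sources used here, so a batch that follows the groups cannot be told apart from them.

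Before the data were examined, 42 gene lists for lung cells, immune signalling and metabolism were fixed from general knowledge. They held 752 genes, of which 684 were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 42 lists, and again with the correlation estimated per list (statmod 1.5.0) and with fry. Camera compares a list with the other genes, and fry asks whether its genes move one way on balance. Named genes were chosen by a rule fixed at the same time: per contrast, the 12 largest rises and 12 largest falls among passing genes whose values did not overlap between groups, Lif, Lifr, Il6st, Osmr, Il6, Stat3 and Socs3 in every contrast, and up to 4 members with the smallest p of each list. Predicted genes, non-coding RNAs and antigen receptor segments were passed over in the first part. The infection response sets held genes with adjusted p under 0.05 and a log2 change of at least 1 between the mean of both infected groups and vehicle. In balanced groups with equal variances the noise of this contrast is independent of that of the anti-LIF contrast, but genes changed under anti-LIF alone can enter the sets. The anti-LIF arrays were also less alike than those of the other groups, so this independence holds only in part. The shift of the sets was tested with camera and with an exact permutation of the mouse means.

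The fit was tested on simulated data with 200 of 18784 genes changed. In the infection contrast it recovered 34.3% of changes of log2 size 0.5, 94.0% of size 1 and 100% of size 2, with 4 false calls (2.56% of calls). In the anti-LIF contrast it recovered 44.8%, 88.1% and 100%, with 8 false calls (4.91%). The simulated genes varied independently, with the same spread in all groups and no shift of whole arrays. These rates therefore need not hold for the real arrays.

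Alternatives fixed before the data were examined were arrays centred on a common median, quantile normalization, the brighter 50% of genes, a variance trend with robust moderation, array weights, a fit of the 6 arrays compared, a replicate block, other ways to treat entries, leaving out each array, and other set tests and set sizes. Cyclic loess between arrays, response sets chosen on infected minus vehicle lungs alone, leaving out anti-LIF replicates 2 and 3 together, and a filter at the 95th percentile of the receptor genes were added after seeing the data. Simulated data with neither an infection nor an anti-LIF effect were drawn 100 times. They gave the correlation, covariance and share of equal signs that shared arrays alone produce. For genes back at the vehicle level under anti-LIF, other draws kept the observed infection changes and left out an anti-LIF effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.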

Results

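Gene expression was measured in whole lung of C57BL/6 mice on 9 Affymetrix arrays, 1 per mouse, 24 h after an intratracheal instillation. The 3 groups held 3 mice each. Vehicle mice received buffer with control IgG, infected mice received 1000000 CFU of E. coli with control IgG, and anti-LIF mice received the same number of bacteria with an antibody that neutralises leukemia inhibitory factor (LIF), a cytokine of the interleukin-6 family. Values were log2 signals for 21212 table entries, which held the 18784 genes tested. Changes are log2 fold changes ± SE with n = 3 mice per group, and the number of arrays limits their precision (median SE 0.12). Vehicle and infected arrays had lower quartiles of 3.69 to 3.74 and upper quartiles of 7.10 to 7.13. The anti-LIF arrays had lower quartiles of 3.82, 4.01 and 4.11 in replicates 1 to 3, and upper quartiles of 7.08, 6.97 and 6.89. The median of 1294 olfactory, vomeronasal and taste receptor genes, which a lung hardly uses, was 2.44 to 2.48 in the vehicle and infected arrays and 2.55, 2.74 and 3.02 in the anti-LIF arrays. Of these genes 95% had a mean signal up to 3.90, so a group mean under 3.90 was taken as near background. Between vehicle and infected arrays, a rise from near background is given as at least the measured size. A rise into the anti-LIF arrays is given as measured, since their receptor-gene medians lay higher and part of it may be background.

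**Figure D1:**
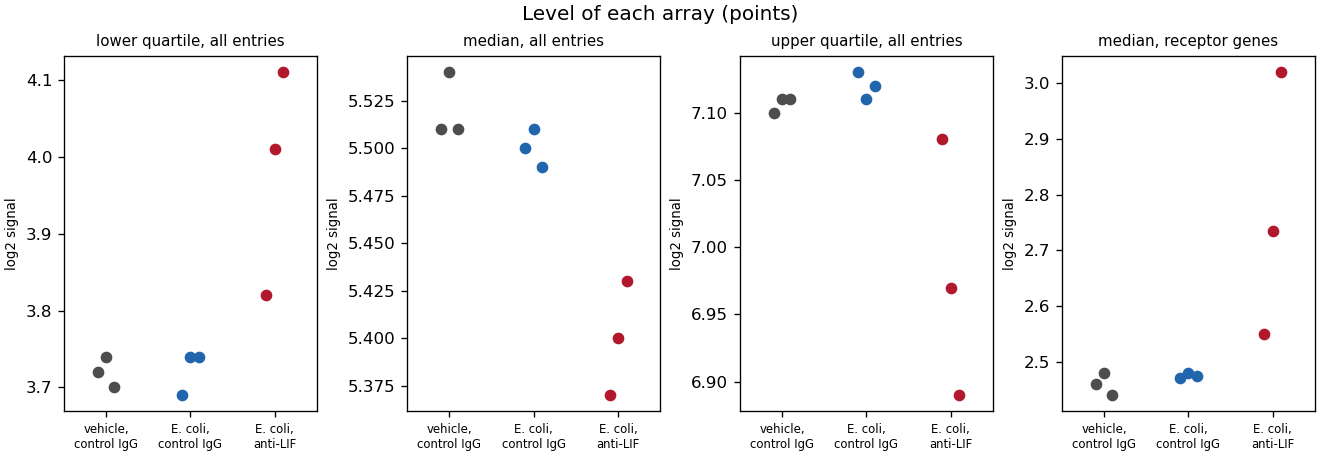
Lower quartile, median and upper quartile of the log2 signal of each array and the median of the receptor genes (y axis, log2 signal) for the 9 arrays (x axis, 3 per group). The anti-LIF arrays had lower quartiles of 3.82 to 4.11, above the 3.69 to 3.74 of the other 6 arrays.

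The first comparison asked which genes E. coli changed in the lung when LIF was left active. The neutrophil granule gene Ngp rose by at least 6.39 ± 0.13, from 3.24 ± 0.26, near background, in vehicle to 9.63 ± 0.13 in infected lungs (mean ± SD, n = 3). The neutrophil-attracting chemokine genes Cxcl2 (at least 5.69 ± 0.34) and Ccl3 (4.90 ± 0.26), the interleukin-1 decoy receptor gene Il1r2 (5.17 ± 0.23) and Acod1, which encodes the itaconate-making enzyme of activated macrophages (5.08 ± 0.28), also rose. The acute phase gene Saa3 rose by 4.03 ± 0.68, and Clec4e, a receptor gene for microbial glycolipids, by 4.48 ± 0.26. Among the genes that fell were Lrat, the retinol-esterifying enzyme (-2.35 ± 0.36), the integrin gene Itga8 (-2.08 ± 0.28), the Wnt-binding Sfrp2 (-2.00 ± 0.19) and the alveolar type 1 gene Rtkn2 (-1.95 ± 0.42). In all, 3334 genes changed at adjusted p under 0.05, 1454 up and 1880 down, and 752 of them changed at least 2-fold, 516 up and 236 down. The count of 3334 was 2082, 2122 and 1958 without vehicle replicate 1, 2 or 3, and 2105 and 1835 without infected replicate 2 or 3. It was higher, 8797, with array weights and 5156 in a fit of the 6 arrays compared. Without infected replicate 3, 142 genes fell at least 2-fold instead of 236.

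**Figure D2:**
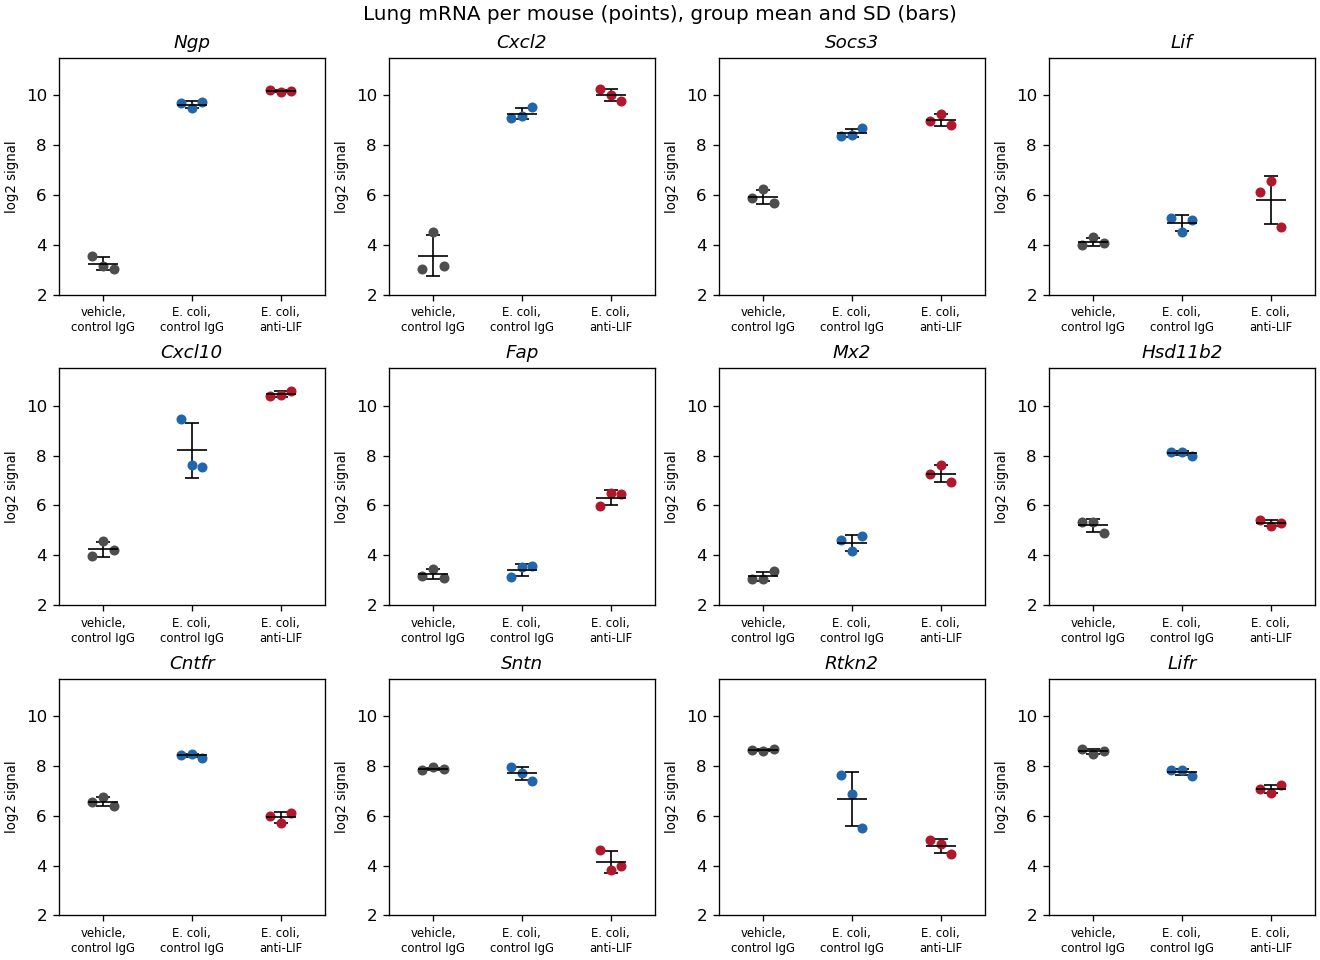
Log2 signal (y axis) of 12 named genes in each of the 9 mice (points), with group mean and SD (bars, n = 3). Ngp stood at 3.24 in vehicle and 9.63 in infected lungs, and Hsd11b2 at 5.20, 8.09 and 5.30 in vehicle, infected and anti-LIF lungs.

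Marker genes of granulocytes and genes of recruitment rose as groups. All 25 measured neutrophil marker genes rose (median 3.03), among them Mmp8 (3.84 ± 0.19), a collagenase, S100a8 (3.14 ± 0.17), a calprotectin subunit, and the activating receptor gene Trem1 (3.92 ± 0.22). The list passed camera with adjusted p = 2.19e-31, and adjusted p = 0.0992 with an estimated correlation. Of 9 neutrophil chemoattractant and growth factor genes, 6 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 4.24e-08, and adjusted p = 0.115 with an estimated correlation). Single list members given without a value were named after their values were seen. Of 20 other chemokine genes, 11 rose, including Ccl2 (4.43 ± 0.42), which attracts monocytes, and Cxcl9 (3.76 ± 0.23), which attracts T cells, and 2 fell, Cxcl12 and Cx3cl1 (14 and 2 adjusted over the list alone, adjusted p = 1.65e-08, and adjusted p = 0.115 with an estimated correlation). Of 19 antimicrobial protein genes, 10 rose, with 10 up and 2 down adjusted over the list alone (adjusted p = 6.44e-08, and adjusted p = 0.0992 with an estimated correlation). Of 19 monocyte and inflammatory macrophage markers, 11 rose, among them Vcan (2.68 ± 0.19), a matrix proteoglycan, and Plac8 (2.25 ± 0.16), with 13 up and 1 down adjusted over the list alone (adjusted p = 8.80e-10, and adjusted p = 0.135 with an estimated correlation).

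Cytokine, interferon and NF-kB genes rose in infected lungs. All 22 type I interferon response genes rose (median 1.62), with the antiviral gene Ifit1 up by 2.35 ± 0.11 and Rtp4 by 1.96 ± 0.14 (adjusted p = 9.99e-29, and adjusted p = 0.0992 with an estimated correlation). Of 20 interferon gamma response genes, 15 rose and Ciita, the regulator of MHC class II genes, fell, with the same counts adjusted over the list alone. Ciita (-0.46 ± 0.12) did not pass without vehicle replicate 1 (-0.37) or 2 (-0.49) or infected replicate 1 (-0.41) or 3 (-0.44). The guanylate-binding gene Gbp5 rose by 2.05 ± 0.11. This list was the 1 of 42 that still passed with an estimated correlation (adjusted p = 0.0186, against 3.04e-16 with the preset correlation). Of 20 NF-kB feedback and target genes, 17 rose (18 adjusted over the list alone, median 1.27), including Tnfaip3, a brake on NF-kB (2.72 ± 0.14), and Nfkbiz (1.99 ± 0.17), with adjusted p = 4.46e-18, and adjusted p = 0.115 with an estimated correlation. Inflammatory cytokine genes split into 8 that rose, 1 that fell (Il18) and 11 that did not pass, with 9 up and 1 down adjusted over the list alone. Il1b rose by 3.87 ± 0.22 and Tnf by 3.97 ± 0.30 (list adjusted p = 9.88e-07, and adjusted p = 0.0992 with an estimated correlation).

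Some genes of the LIF family and most listed STAT3 target and acute phase genes rose in infected lungs. Lif itself was 4.13 ± 0.16 in vehicle and 4.88 ± 0.30 in infected lungs (SD, n = 3), a difference of 0.75 ± 0.39 that did not pass (adjusted p = 0.260). The fit takes a common spread for all groups, and Lif varied most in anti-LIF lungs (SD 0.97), which are not part of this comparison. This result therefore cannot exclude a rise of Lif in infection. The LIF receptor gene Lifr fell by 0.83 ± 0.11, while the related receptor and cytokine genes Osmr (0.88 ± 0.12), Osm (1.75 ± 0.22), Cntfr (1.86 ± 0.13) and Il6 (at least 3.84 ± 0.74) rose, and the shared receptor chain Il6st did not pass (0.17 ± 0.12). Of the 12 measured genes of this family, 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0043, and adjusted p = 0.0992 with an estimated correlation). STAT3, a transcription factor that LIF and other cytokines activate, had 23 listed target genes, of which 20 rose (21 adjusted over the list alone, median 1.19, adjusted p = 3.01e-22, and adjusted p = 0.0992 with an estimated correlation). Socs3, the feedback inhibitor of this pathway, rose by 2.56 ± 0.16, the protease inhibitor Timp1 by 2.92 ± 0.16, and Stat3 by 0.51 ± 0.10. Of 21 acute phase genes, 17 rose (18 adjusted over the list alone, median 1.38), among them Orm1 (3.65 ± 0.35) and Saa4 (at least 1.65 ± 0.11), with adjusted p = 1.13e-14, and adjusted p = 0.0992 with an estimated correlation.

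Markers of several resident lung cells fell in infection, in the same whole-lung samples in which all 25 neutrophil markers rose (median 3.03). Of 26 endothelial markers, 10 fell and none rose (15 adjusted over the list alone, median -0.39), including the VEGF receptor gene Kdr (-0.60 ± 0.10) and Tie1 (-0.81 ± 0.14), with adjusted p = 1.86e-06, and adjusted p = 0.168 with an estimated correlation. Ciliated cell markers fell in 9 of 19 (14 adjusted over the list alone, median -0.62), such as the dynein gene Dnaic1 (-0.93 ± 0.12), with adjusted p = 1.23e-06, and adjusted p = 0.263 with an estimated correlation. Among 21 alveolar type 2 and surfactant genes, 8 fell, with the phospholipid transporter Abca3 at -0.69 ± 0.15, and Ctsh rose, against 11 and 1 adjusted over the list alone (adjusted p = 5.17e-04, and adjusted p = 0.393 with an estimated correlation). Alveolar type 1 markers fell in 4 of 17 and rose in 2, Krt7 and Pdpn (7 and 2 adjusted over the list alone, adjusted p = 0.0095, and adjusted p = 0.393 with an estimated correlation). Smooth muscle markers fell in 4 of 11, also adjusted over the list alone (adjusted p = 9.28e-04, and adjusted p = 0.393 with an estimated correlation), and cardiac muscle genes in 2 of 14, with 7 adjusted over the list alone (adjusted p = 8.98e-04, and adjusted p = 0.420 with an estimated correlation). Of 16 B cell markers, 10 fell, including Ms4a1 (-1.60 ± 0.16), the gene of CD20, and the IgE receptor gene Fcer2a rose (11 and 1 adjusted over the list alone, adjusted p = 3.94e-06, and adjusted p = 0.230 with an estimated correlation). Xenobiotic metabolism genes fell in 7 of 20, among them Fmo1 (-0.82 ± 0.14), with 11 down and 1 up adjusted over the list alone (adjusted p = 1.35e-04, and adjusted p = 0.420 with an estimated correlation). Several counts moved with single arrays. Without vehicle replicate 1 the falling genes numbered 4 alveolar type 2, 5 ciliated, 2 smooth muscle and 4 xenobiotic genes. Without vehicle replicate 2 they were 5 alveolar type 2 and 2 smooth muscle genes. Without vehicle replicate 3 they numbered 6 endothelial, 4 alveolar type 2, 2 alveolar type 1, 2 smooth muscle and 3 xenobiotic genes. Without infected replicate 2 they were 4 alveolar type 2, 2 smooth muscle and 4 xenobiotic genes. Without infected replicate 3 they were 4 ciliated, 4 alveolar type 2, 2 alveolar type 1, 2 smooth muscle and 3 xenobiotic genes. Without infected replicate 1, 4 cardiac genes fell, and without anti-LIF replicate 1, 7 alveolar type 1 genes. Without anti-LIF replicate 3 the numbers were 9 alveolar type 1, 8 smooth muscle, 7 cardiac and 14 xenobiotic genes.

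Stress, clotting and hormone-responsive genes also rose in infected lungs. Of 15 glucocorticoid-responsive genes, 9 rose, also adjusted over the list alone, including the metallothionein gene Mt1 (1.68 ± 0.10) and Fkbp5 (1.96 ± 0.23), with adjusted p = 5.49e-08, and adjusted p = 0.115 with an estimated correlation. Coagulation and fibrinolysis genes rose in 9 of 15 and 1 fell, Vwf, with F10, clotting factor X, up by 3.14 ± 0.39 (10 and 2 adjusted over the list alone, adjusted p = 3.33e-05, and adjusted p = 0.115 with an estimated correlation). The oxidative stress list had 8 of 15 genes up, led by the cystine transporter Slc7a11 (3.62 ± 0.34), with 11 up and 1 down adjusted over the list alone (adjusted p = 4.21e-06, and adjusted p = 0.135 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 18, among them the glucose transporter Slc2a1 (1.23 ± 0.15), and fell in 2, Pdk1 and P4ha1 (10 and 2 adjusted over the list alone, adjusted p = 1.86e-04, and adjusted p = 0.0992 with an estimated correlation). Cell death genes rose in 9 of 20, with the death receptor gene Fas up by 1.12 ± 0.09 (11 up and 1 down adjusted over the list alone, adjusted p = 7.26e-07, and adjusted p = 0.135 with an estimated correlation). Immediate early and heat shock genes rose in 6 of 14, also adjusted over the list alone, with Junb up by 1.35 ± 0.12 (adjusted p = 5.98e-04, and adjusted p = 0.368 with an estimated correlation). Of 9 anti-apoptotic genes, 5 rose, such as Birc3 (1.31 ± 0.13), against 5 up and 2 down adjusted over the list alone (adjusted p = 0.0348, and adjusted p = 0.143 with an estimated correlation). This anti-apoptotic call ended after cyclic loess (adjusted p = 0.0849) and quantile normalization (adjusted p = 0.0783). It also ended in at least 1 run that left out a single array. Rising genes numbered 3 anti-apoptotic without vehicle replicate 1, vehicle replicate 3, infected replicate 2 or infected replicate 3, 5 oxidative stress without vehicle replicate 2 or 3 or infected replicate 2 or 3, and 5 hypoxia without vehicle replicate 3 or infected replicate 2 or 3.

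The other 15 lists did not pass camera in infection (adjusted p from 0.0638 to 0.979). MHC class II genes fell in 4 of 12 and none rose (adjusted p = 0.0638), including H2-Ob (-1.13 ± 0.18), and circadian clock genes fell in 6 of 15, with the clock output gene Dbp at -1.18 ± 0.14, while Cry1 rose (adjusted p = 0.0688). The same counts held for both lists adjusted over the list alone, and the MHC class II list passed after cyclic loess (adjusted p = 0.0285) and quantile normalization (adjusted p = 0.0489). Alveolar macrophage markers rose in 2 of 17, Ctsk and Lpl, and fell in 3. T and NK cell markers rose in 2 of 23, with the granzyme gene Gzmb at 1.15 ± 0.21, and fell in 1, Cd2. Dendritic cell markers rose in 4 of 13 and fell in 2, Cd209a and Clec9a. Fibroblast and matrix genes split into 4 up and 4 down of 21, with the collagen cross-linking gene Lox up by 0.92 ± 0.11. Club and secretory cell genes rose in 2 of 19, with the haptoglobin gene Hp at 0.48 ± 0.08, and junction genes rose in 4 and fell in 3 of 20. Epithelial growth and repair factor genes fell in 4 of 20, with the growth factor Fgf10 at -0.82 ± 0.11, cholesterol and fatty acid synthesis genes in 3 of 16 and cell cycle genes in 2 of 28, Bub1 and E2f1. Adjusted over the list alone, 5 growth factor and 4 cholesterol genes fell, and the other lists from alveolar macrophages on had the counts given. The median and the camera direction differed in sign for club cell (-0.07), junction (-0.05), growth factor (0.0050), cholesterol (0.0067) and reference genes (0.02). No gene passed among 12 mast cell and eosinophil, 4 red blood cell, 9 adipose and 8 reference genes. Without vehicle replicate 1 the falling MHC class II genes were 2 and circadian genes 3, and rising junction genes 1 and falling ones 1. Without vehicle replicate 2 the numbers were 2, 3, 1 and 1 in that order. Without vehicle replicate 3, junction genes were 1 up and 1 down, falling fibroblast genes 2, growth factor genes 2, cholesterol genes 1 and cell cycle genes 5. Without infected replicate 2, circadian genes were 3, junction genes 1 up and 1 down and growth factor genes 2. Without infected replicate 3, MHC class II genes were 2, circadian genes 3, junction genes 2 up and 1 down, growth factor genes 2 and alveolar macrophage genes 1. Without infected replicate 1, 5 T and NK cell genes rose, and without anti-LIF replicate 3, 6 club cell genes fell and 4 growth factor genes rose.

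**Figure D3:**
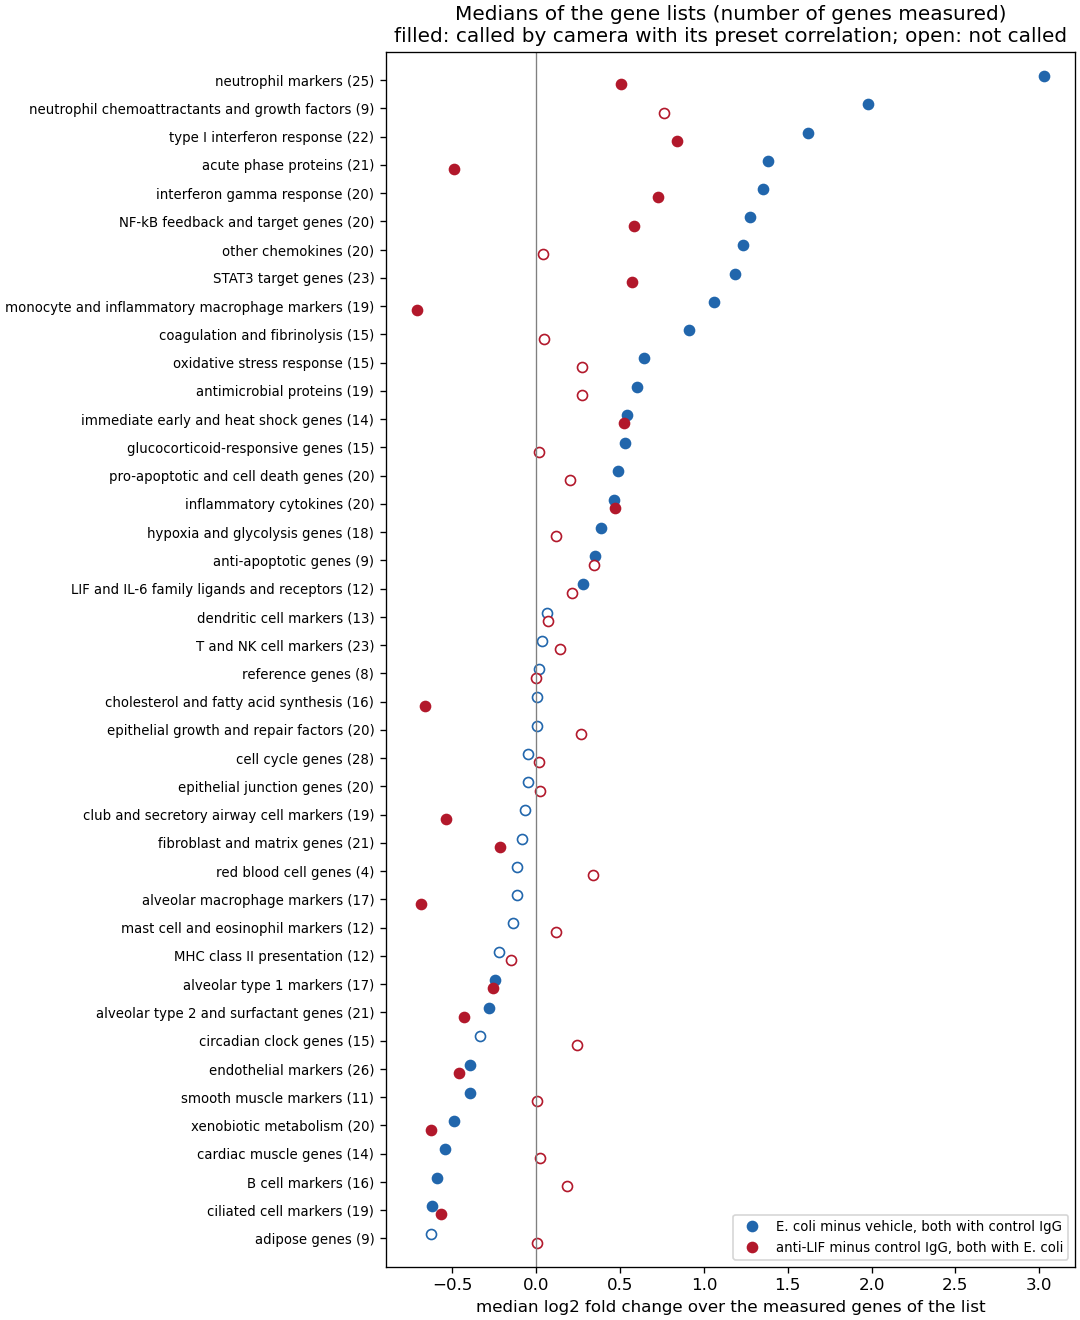
Median log2 fold change (x axis) of the members of each of 42 gene lists (y axis) for infected minus vehicle lungs and for anti-LIF minus control IgG infected lungs, filled where camera with the preset correlation gave an adjusted p under 0.05. The type I interferon list had medians of 1.62 and 0.84, the ciliated cell list -0.62 and -0.57.

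The second comparison, for which the series was made, asked what LIF neutralisation changed in infected lungs. Fap, a serine protease of activated fibroblasts, rose by 2.91 ± 0.17, from 3.40 ± 0.25, near background, in infected to 6.31 ± 0.30 in anti-LIF lungs (SD, n = 3). The interferon-induced genes Mx2 (2.77 ± 0.19) and Cxcl10 (2.25 ± 0.43) rose with it. Also raised were the stefin gene Stfa1 (2.37 ± 0.28), Tnfrsf11b, which encodes osteoprotegerin (2.09 ± 0.19), Il12a (2.07 ± 0.31), Il24 (1.98 ± 0.21, from near background) and the cornified envelope gene Sprr1a (1.99 ± 0.16). The ciliary genes Sntn (-3.56 ± 0.20) and Rsph4a (-2.80 ± 0.15), the cholecystokinin receptor gene Cckar (-2.88 ± 0.12), Hsd11b2, which inactivates glucocorticoids (-2.79 ± 0.13), and the proton pump gene Atp6v0d2 (-2.70 ± 0.28) fell. In all, 9157 genes changed, 5001 up and 4156 down (54.6% up), and of 1201 genes that changed at least 2-fold 263 rose and 938 fell. The majority of rises did not hold in every setting. Without infected replicate 1, 6300 genes passed, 2827 of them up (44.9%), and the rising genes numbered 2909 of 6217 without infected replicate 2 and 2947 of 6362 without anti-LIF replicate 2. The share up was 48.7% without infected replicate 3, 34.5% among the brighter 50% of genes, 40.7% with array weights and 45.5% in a fit of the 6 arrays compared. These changes came with the shifted quartiles of the anti-LIF arrays: the median change of all genes was 0.11, and it moved by -0.10 after cyclic loess, by 0.10 with arrays centred on a common median and by -0.08 after quantile normalization. With centred arrays 11591 genes passed, 70.5% of them up. After cyclic loess, chosen after seeing the data, 7523 passed, 47.7% of them up, with 6343 of the 9157 passing in the same direction and 0 in the opposite one. In 10 equal groups by vehicle level, the median change was 0.20, 0.30, 0.34, 0.28 and 0.09 in groups 1 to 5, the dimmest first, and -0.06, -0.16, -0.18, -0.21 and -0.23 in groups 6 to 10. List medians under anti-LIF are given relative to the median of all genes, which leaves this gradient in. They are also given relative to genes of like vehicle level (a smooth curve), a measure chosen after seeing the data.

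Interferon, NF-kB and STAT3 target genes rose under anti-LIF, in the 3 arrays whose lower quartiles were 3.82, 4.01 and 4.11. Of 22 type I interferon response genes, 16 rose, with a median 0.73 above that of all genes, including Stat2 (0.91 ± 0.09) and the RNA sensor gene Ifih1 (0.86 ± 0.09). Adjusted over the list alone, 17 rose and 1 fell (adjusted p = 2.08e-04, and adjusted p = 0.715 with an estimated correlation). Of 20 interferon gamma response genes, 15 rose, also adjusted over the list alone, with the peptide transporter Tap1 up by 1.25 ± 0.10 and Gbp5 by 1.45 ± 0.11 (relative median 0.61, adjusted p = 1.45e-04, and adjusted p = 0.257 with an estimated correlation). Of 20 NF-kB feedback and target genes, 14 rose (15 adjusted over the list alone, relative median 0.47), including the adhesion molecule Vcam1 (1.14 ± 0.12) and Cd40 (1.01 ± 0.11), with adjusted p = 3.51e-04, and adjusted p = 0.715 with an estimated correlation. STAT3 target genes rose in 16 of 23 and fell in 2, Serpina3n and Il6st (17 and 2 adjusted over the list alone, relative median 0.46, adjusted p = 0.0036, and adjusted p = 0.715 with an estimated correlation), with the transcription factor genes Cebpd up by 1.29 ± 0.17 and Myc by 0.97 ± 0.15. Inflammatory cytokine genes rose in 9 of 20, and Il18 fell, also adjusted over the list alone (relative median 0.35, adjusted p = 0.0286, and adjusted p = 0.707 with an estimated correlation). Immediate early and heat shock genes rose in 6 of 14, also adjusted over the list alone, with Fosb up by 2.51 ± 0.30 (relative median 0.41, adjusted p = 0.0455, and adjusted p = 0.764 with an estimated correlation). Neutrophil markers rose in 7 of 25, such as the histamine-forming enzyme Hdc (1.75 ± 0.18), with 4 adjusted over the list alone (relative median 0.39, adjusted p = 0.0238, and adjusted p = 0.795 with an estimated correlation). Relative to genes of like vehicle level the medians were 0.84 and 0.86 for type I interferon and interferon gamma genes, 0.73 for NF-kB, 0.86 for STAT3 target, 0.35 for cytokine, 0.67 for immediate early and 0.50 for neutrophil genes. Of the neutrophil markers, 3 rose without infected replicate 1 and 4 without anti-LIF replicate 1 or 2. With centred arrays the cytokine, immediate early and neutrophil lists each had adjusted p = 0.0908. Without infected replicate 1 they had 0.0935, 0.0722 and 0.158, and without anti-LIF replicate 1 they had 0.148, 0.301 and 0.250. The immediate early list had 0.0820 without anti-LIF replicate 2.

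Within the LIF family, changes under anti-LIF went both ways. The signal of Lif was 5.79 ± 0.97 in anti-LIF and 4.88 ± 0.30 in infected lungs (SD, n = 3), a difference that did not pass (0.91 ± 0.39, adjusted p = 0.0753) except without anti-LIF replicate 3 (1.46, adjusted p = 6.05e-04). Cntfr, the receptor chain for ciliary neurotrophic factor, fell by 2.49 ± 0.13 and Lifr by 0.67 ± 0.11, while the ligand genes Clcf1 (0.93 ± 0.15) and Osm (0.92 ± 0.22) rose. Il6 (1.38 ± 0.74), Osmr (0.20 ± 0.12) and Stat3 (0.24 ± 0.10) did not pass, though without anti-LIF replicate 3 Il6 (2.07) and Stat3 (0.34) did. Socs3 rose by 0.53 ± 0.16 and Il6st fell by 0.40 ± 0.12. Socs3 did not pass with array weights (adjusted p = 0.197), nor did Il6st (adjusted p = 0.0926), which also had adjusted p = 0.0726 with centred arrays and 0.0664 in a fit of the 6 arrays compared. Neither gene passed without infected replicate 1 (0.46 and -0.33), infected replicate 2 (0.49 and -0.42) or anti-LIF replicate 2 (0.41 and -0.42). Of the 12 genes of the family 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.880), and 5 rose without anti-LIF replicate 3. Of 21 acute phase genes, 8 fell and 1 rose, also adjusted over the list alone, with Saa4 (-1.65 ± 0.11, down to a signal near background), Orm2 (-2.40 ± 0.48) and the copper carrier Cp (-0.49 ± 0.10) among those that fell (relative median -0.60, and -0.44 relative to genes of like vehicle level, adjusted p = 0.0072, and adjusted p = 0.715 with an estimated correlation). With array weights Orm2 (adjusted p = 0.128) and Cp (adjusted p = 0.0755) did not pass.

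Macrophage and monocyte markers fell under anti-LIF. Of 17 alveolar macrophage markers, 10 fell and Cd9 rose, also adjusted over the list alone, with the lipoprotein lipase gene Lpl down by 1.46 ± 0.10 and the integrin gene Itgax by 0.81 ± 0.11 (relative median -0.80, adjusted p = 0.0024, and adjusted p = 0.257 with an estimated correlation). Of 19 monocyte and inflammatory macrophage markers, 11 fell and 3 rose, also adjusted over the list alone, including the complement gene C1qb (-1.20 ± 0.20) and the macrophage surface gene Adgre1 (-0.88 ± 0.16), with relative median -0.82 (adjusted p = 0.0170, and adjusted p = 0.747 with an estimated correlation). The monocyte list did not pass after cyclic loess (adjusted p = 0.107) or without infected replicate 3 (adjusted p = 0.0740). Relative to genes of like vehicle level the medians were -0.62 for alveolar macrophage and -0.63 for monocyte markers. Receptor-gene medians in these 3 arrays were 2.55, 2.74 and 3.02.

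Markers of epithelium and endothelium fell under anti-LIF, together with the lower upper quartiles of these arrays (7.08, 6.97 and 6.89). Ciliated cell markers fell in 12 of 19 (13 adjusted over the list alone, relative median -0.68), with the ciliogenesis regulator Foxj1 at -0.51 ± 0.09 and Tekt4 at -1.64 ± 0.17 (adjusted p = 2.08e-04, and adjusted p = 0.707 with an estimated correlation). Of 26 endothelial markers, 13 fell and Robo4 rose (15 and 2 adjusted over the list alone, relative median -0.58), including the transcription factor gene Erg (-1.66 ± 0.13) and Ramp2 (-1.91 ± 0.24), with adjusted p = 2.08e-04, and adjusted p = 0.707 with an estimated correlation. Of 21 alveolar type 2 and surfactant genes, 11 fell, also adjusted over the list alone, such as the phosphate transporter Slc34a2 (-0.91 ± 0.11) and the surfactant lipid enzyme Lpcat1 (-0.85 ± 0.12), with relative median -0.55 (adjusted p = 2.08e-04, and adjusted p = 0.707 with an estimated correlation). Alveolar type 1 markers fell in 7 of 17, also adjusted over the list alone, including the water channel Aqp5 (-0.57 ± 0.13), with relative median -0.37 (adjusted p = 0.01, and adjusted p = 0.707 with an estimated correlation), and 11 fell without anti-LIF replicate 1. Club and secretory cell markers fell in 9 of 19, with Cldn10 at -1.30 ± 0.20, and Upk3a rose (10 and 1 adjusted over the list alone, relative median -0.65, adjusted p = 0.0072, and adjusted p = 0.707 with an estimated correlation). Fibroblast and matrix genes fell in 7 of 21 and Col5a1 rose (6 and 1 adjusted over the list alone, relative median -0.33), with Pdgfra at -0.57 ± 0.09 and Pdgfrb at -0.76 ± 0.11, both growth factor receptors (adjusted p = 0.0142, and adjusted p = 0.615 with an estimated correlation). After cyclic loess the alveolar type 1 list (adjusted p = 0.105) and the fibroblast list (adjusted p = 0.204) did not pass. Neutrophil markers rose in 7 of 25 in the same samples, a share near that of all genes (5001 of 18784). Part of these falls followed the vehicle level: relative to genes of like level the medians were -0.37 for ciliated, -0.22 for endothelial, -0.16 for alveolar type 2 and -0.26 for club cell markers. They were 0.05 for alveolar type 1 and 0.03 for fibroblast genes, which thus lay no lower than other genes of their level. Smooth muscle markers did not pass as a list (adjusted p = 0.979), and their median lay -0.11 relative to all genes but 0.06 after cyclic loess and 0.23 relative to genes of like vehicle level.

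Cholesterol and xenobiotic genes fell under anti-LIF as lists. Of 16 cholesterol and fatty acid synthesis genes, 11 fell and Elovl6 rose, also adjusted over the list alone, with the sterol enzymes Lss (-1.36 ± 0.16), Sqle (-1.02 ± 0.12) and Fdps (-1.03 ± 0.13) among them (relative median -0.78, adjusted p = 3.51e-04, and adjusted p = 0.615 with an estimated correlation). Xenobiotic metabolism genes fell in 11 of 20 (13 adjusted over the list alone, relative median -0.74), including the alcohol dehydrogenase Adh1 (-2.01 ± 0.19) and Fmo1 (-1.17 ± 0.14), with adjusted p = 3.51e-04, and adjusted p = 0.715 with an estimated correlation. Relative to genes of like vehicle level the medians were -0.40 and -0.39. The xenobiotic count was 6 without infected replicate 1 and 7 without anti-LIF replicate 3. The lower quartiles of the anti-LIF arrays lay at 3.82 to 4.11 beside these changes.

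The other 24 lists did not pass under anti-LIF (adjusted p from 0.137 to 0.991). In several of them some members rose and others fell, but so did 5001 and 4156 of all 18784 genes. Member counts of these 24 lists are to be read against that share and do not by themselves set a list apart. Neutrophil chemoattractant and growth factor genes rose in 3 of 9, among them Csf2, a growth factor gene for granulocytes and macrophages (1.01 ± 0.20), with adjusted p = 0.137, but adjusted p = 0.0291 after cyclic loess, 0.0362 after quantile normalization and 0.01 without anti-LIF replicate 3. Other chemokine genes rose in 4 of 20, such as Cxcl11 (1.73 ± 0.22), and fell in 2, Cxcl12 (-0.80 ± 0.10) and Cxcl14. Of 19 antimicrobial genes 8 rose and 3 fell, Reg3g among them (-1.12 ± 0.22), and of 12 MHC class II genes 4 fell, such as Ifi30 (-0.81 ± 0.11), a reductase gene of antigen processing. Anti-apoptotic genes rose in 6 of 9, with Birc2 at 0.90 ± 0.12, cell death genes in 8 of 20, with Fas at 0.51 ± 0.09, and oxidative stress genes in 6 of 15, with Txnrd1 at 1.35 ± 0.20. These lists passed after cyclic loess (adjusted p = 0.0258, 0.0370 and 0.0184), and the cell death list after quantile normalization (adjusted p = 0.0308). Growth and repair factor genes rose in 7 of 20, with Sox9 at 1.81 ± 0.21, and fell in 6, with Vegfa at -0.59 ± 0.08 and Fgf7 at -1.77 ± 0.35. Junction genes rose in 3 of 20, with the claudin gene Cldn4 at 1.78 ± 0.26, and fell in 6. Clock genes rose in 5 of 15, with Arntl at 1.09 ± 0.22, and fell in 3, with Per3 at -1.17 ± 0.18. Adjusted over the list alone, 9 antimicrobial, 7 cell death, 9 growth factor, 2 junction and 7 clock genes rose and 3 MHC class II genes fell, and the other counts were as given. Reg3g did not pass with array weights (-1.01, adjusted p = 0.0637). Single arrays moved some of these counts: without infected replicate 1, 2 antimicrobial genes rose and 1 fell, 2 MHC class II genes fell, 3 anti-apoptotic and 5 cell death genes rose and 3 growth factor genes fell. Without infected replicate 2 those numbers were 4 antimicrobial genes up, 2 MHC class II genes, 2 anti-apoptotic genes, 5 cell death genes and 3 growth factor genes. Without anti-LIF replicate 2, 1 chemoattractant, 2 other chemokine, 4 antimicrobial and 2 anti-apoptotic genes rose and 1 antimicrobial and 2 MHC class II genes fell. Without anti-LIF replicate 3, 7 chemoattractant and 6 junction genes rose and 2 MHC class II genes fell, and without vehicle replicate 2, 4 other chemokine genes fell.

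Lymphocyte, proliferation and the remaining lists did not pass as groups under anti-LIF. Cell cycle genes rose in 4 of 28 and fell in 5, with the replication genes Mcm5 (-0.63 ± 0.11) and Top2a (-0.84 ± 0.18) among the latter. T and NK cell markers rose in 7 of 23, with Cd3d at 0.60 ± 0.11 from a signal near background, and fell in 1, Cd27, against 1 and 0 adjusted over the list alone. B cell markers rose in 3 of 16, with Pax5 at 0.52 ± 0.10, and fell in 4, with Fcer2a at -2.13 ± 0.18. Dendritic cell markers rose in 5 of 13, with Ccr7 at 0.68 ± 0.13, and mast cell and eosinophil markers rose in 3 of 12 and fell in 2, Ear6 and Kit. Hypoxia and glycolysis genes rose in 4 of 18, with Hk2 at 1.19 ± 0.21, and fell in 4, with Bnip3 at -0.96 ± 0.15. Coagulation genes rose in 4 of 15, with the tissue factor gene F3 at 0.79 ± 0.14, and fell in 3, with F7 at -1.35 ± 0.15. Glucocorticoid-responsive genes rose in 2 of 15 and fell in 2, Zbtb16 (-0.68 ± 0.13) and Klf15 (-0.89 ± 0.22). Smooth muscle genes rose in 2 of 11, cardiac genes in 1 of 14 and red blood cell genes in 2 of 4, with the anion exchanger Slc4a1 at 0.49 ± 0.12, and 0 of 9 adipose genes passed. Adjusted over the list alone, 1 cell cycle, 5 coagulation, 1 glucocorticoid-responsive, 0 smooth muscle and 0 cardiac genes rose and 3 cell cycle genes fell. With array weights Cd3d, Pax5, Ccr7, Ear6, Slc4a1, Top2a, Zbtb16 and Klf15 did not pass, and Cd3d had adjusted p = 0.0501 after cyclic loess. Of 8 reference genes, Sdha (-0.82 ± 0.07), Gusb (-1.05 ± 0.10) and Tfrc (-1.20 ± 0.14) fell and Hprt rose (0.30 ± 0.07), and their median lay -0.11 relative to all genes but 0.05 after cyclic loess and 0.31 relative to genes of like vehicle level. Median and mean had opposite signs for B cell (0.18 and -0.09), cell cycle (0.02 and -0.05), coagulation (0.05 and -0.02), glucocorticoid-responsive (0.02 and -0.05) and mast cell genes (0.12 and -0.04). The camera direction turned in at least 1 scaling for the lists of other chemokines, smooth muscle, junction, hypoxia, coagulation, glucocorticoid, mast cell, B cell, adipose and clock genes. Without infected replicate 1, rising genes numbered 1 T and NK, 1 B, 3 dendritic, 1 mast cell and 1 cell cycle gene. Without anti-LIF replicate 2 they were 3 T and NK, 1 B, 3 dendritic, 1 mast cell and 1 cell cycle gene. Falling genes numbered 3 T and NK and 3 cell cycle genes without infected replicate 1, 1 B and 3 cell cycle genes without infected replicate 2, and 2 B and 3 cell cycle genes without infected replicate 3. They were 1 B, 3 cell cycle and 4 glucocorticoid-responsive genes without anti-LIF replicate 3 and 3 cell cycle genes without vehicle replicate 2. Without infected replicate 2, 2 T and NK, 1 mast cell and 1 cell cycle gene rose, and without vehicle replicate 1, 1 mast cell and 2 cell cycle genes. Rising cell cycle genes were 1 without vehicle replicate 2 and 2 without vehicle replicate 3 or infected replicate 3.

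Sets of genes that differed from vehicle in the mean of both infected groups were also compared between these groups. The 713 genes raised at least 2-fold in that mean, among them Ngp and Cxcl2, had mean levels of 5.83 ± 0.10 in vehicle, 7.36 ± 0.29 in infected and 7.97 ± 0.13 in anti-LIF lungs (SD, n = 3). Their mean difference between anti-LIF and control IgG was 0.60, with 398 genes higher and 21 lower. The 823 lowered genes had mean levels of 7.25 ± 0.03, 6.42 ± 0.23 and 5.46 ± 0.14, a mean difference of -0.97, with 1 gene higher and 646 lower. Camera gave p = 1.26e-13 and p = 1.04e-47 across genes, and p = 0.244 and p = 0.0389 with an estimated correlation. A 2-sided exact permutation test of the mouse means gave p = 0.1 for both sets, the smallest that 3 against 3 mice allow. The lower quartiles of the anti-LIF arrays lay at 3.82 to 4.11 beside these shifts. Genes changed under anti-LIF alone enter these sets, such as Sntn (7.88, 7.69 and 4.14 in vehicle, infected and anti-LIF lungs), so part of both shifts follows from the choice of the sets. In infection itself, 656 of the 713 and 622 of the 823 passed in the same direction. With sets chosen on infected minus vehicle lungs alone, added after seeing the data, the 516 genes raised at least 2-fold shifted by 0.35 under anti-LIF, with 202 higher and 41 lower. The 236 lowered genes shifted by -0.38, with 12 higher and 86 lower. Camera gave p = 1.65e-04 and p = 5.42e-07 for these sets, and p = 0.531 and p = 0.394 with an estimated correlation. Shared infected arrays moved sets chosen this way by -0.03 and 0.06 in simulated data without an anti-LIF effect. Of the 41 genes, 16 did not pass against vehicle under anti-LIF (differences of -0.56 to 0.91), among them Hsd11b2, Saa4 and Orm2, and, named after their values were seen, the apolipoprotein gene Apod (-1.96 ± 0.22) and Chl1 (-1.61 ± 0.16). Saa4 and Chl1 were near background in vehicle and anti-LIF lungs. Without infected replicate 1, 84 of the genes raised at least 2-fold in infection were lower under anti-LIF.

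**Figure D4:**
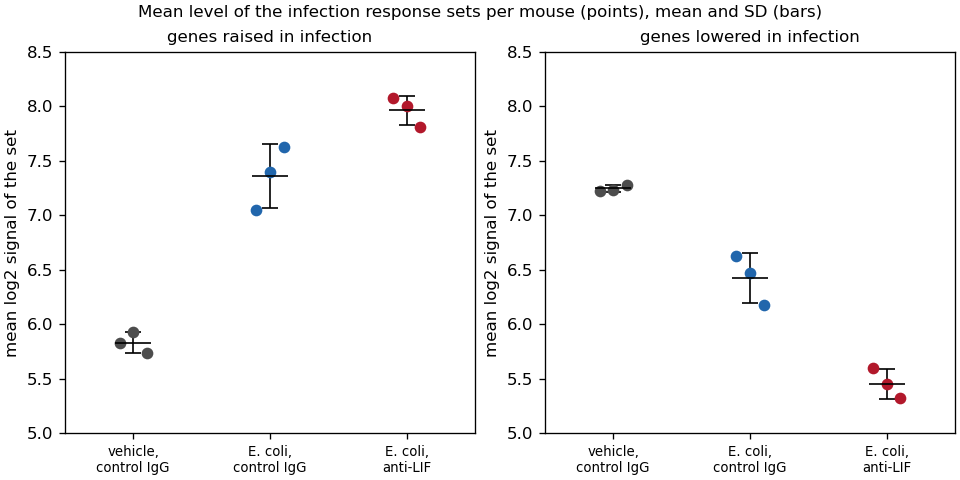
Mean log2 signal (y axis) of the 713 raised and 823 lowered genes in each of the 9 mice (points), with group mean and SD (bars, n = 3). The raised genes stood at 5.83, 7.36 and 7.97 and the lowered genes at 7.25, 6.42 and 5.46 in vehicle, infected and anti-LIF lungs.

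The third comparison set infected lungs with LIF neutralised against vehicle lungs. Ngp (6.93 ± 0.13), Cxcl2 (6.45 ± 0.34) and Il6 (5.22 ± 0.74), all near background in vehicle, rose, as did Cxcl10 (6.22 ± 0.43) and Acod1 (5.88 ± 0.28). Rtkn2 (-3.85 ± 0.42), Sntn (-3.74 ± 0.20), the incretin receptor gene Glp1r (-3.62 ± 0.23) and the transcription factor gene Etv5 (-3.52 ± 0.34) fell. Lif (1.66 ± 0.39), Osmr (1.09 ± 0.12), Stat3 (0.75 ± 0.10) and Socs3 (3.09 ± 0.16) rose. Lifr fell from 8.58 ± 0.10 to 7.08 ± 0.16 (SD, n = 3), while Il6st did not pass (-0.23 ± 0.12). All 25 neutrophil markers, 22 type I interferon and 20 NF-kB genes rose, and 18 of 19 ciliated, 18 of 21 alveolar type 2 and 21 of 26 endothelial markers fell, also adjusted over the list alone, in the arrays with lower quartiles of 3.82 to 4.11. Camera called 24 of 42 lists, 14 up and 10 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.108 for the interferon gamma response. In all, 11784 genes changed, 6465 up and 5319 down (54.9% up), and 2927 at least 2-fold, 1066 up and 1861 down. With arrays centred on a common median 13743 genes passed, 67.1% of them up, but the share up was 48.3% after quantile normalization, 48.8% after cyclic loess and 39.0% among the brighter 50% of genes. It was 48.4% with array weights and 49.4% without vehicle replicate 3. Both infected groups shared the vehicle arrays, and the changes against vehicle had r = 0.777 across 18784 genes. It was 0.501 in simulated data without an infection or anti-LIF effect, in which shared arrays alone linked them. The covariance was 0.290 against 0.0099 in those data, and 72.8% of genes had the same sign in both against 66.6%. Calls up in both numbered 1252 and down in both 1691, counts that were not set against simulated data, and genes are not independent replicates.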

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

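The tests of resident cell markers, the values relative to genes of like vehicle level and the runs with cyclic loess were chosen after the result was seen, and the other tests of this part before.

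Among named genes, 5 passed as higher than vehicle under control IgG and as lower than vehicle under anti-LIF. These genes were picked for this pattern, so their difference between the 2 infected groups follows from the choice. The difference between anti-LIF and control IgG was -2.49 for Cntfr, -0.71 for Ctsh, -2.13 for Fcer2a, -1.46 for Lpl and -0.78 for Marveld3. Over all genes, 59 passed in both contrasts against vehicle with opposite directions, 45 up under control IgG and down under anti-LIF, and 14 the other way. Among 2426 table entries without exactly 1 gene symbol, which the gene tests left out, 146 passed in infection, 737 under anti-LIF and 1197 in infection under anti-LIF against vehicle.

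The count of 9157 genes changed under anti-LIF came with narrower signal distributions in the anti-LIF arrays. A smooth curve on the vehicle level explained 20.9% (20 to 21.8) of the variance of the anti-LIF change over all genes and 25% (24.1 to 25.9) over the genes that passed, and 7523 genes passed after cyclic loess. This argues against compression as the whole cause, while a partial contribution stays open because the value over passing genes lies at the bound of 25% set beforehand. Of 14093 genes above the receptor-gene level 53.5% passed, 3438 higher and 4095 lower. That share lies past the bound set beforehand against a raised background as the whole cause. It cannot decide the question, because signals were normalised between arrays and a raised background could then also lower brighter genes. For dim genes a raised background cannot be told apart from an effect of the antibody. The receptor genes had a median change of 0.28 (0.27 to 0.30), between the bounds set beforehand. A batch that follows the groups stays open throughout.

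Resident cell markers fell under anti-LIF. A lower share of all resident cells would lower each list alike only if the markers were equally specific and changed for no other reason. That assumption was not tested. Ciliated and smooth muscle markers, the lists farthest apart in mean change, differed by -0.78 (-1.04 to -0.53). In all, 3 of 21 pairs of lists differed beyond the spread between mice (Holm over pairs), also relative to genes of like vehicle level. Under the assumption above, this argues against 1 common loss as the whole cause. Without it, the differences show only that the lists did not fall by equal amounts. In 2 other tests of this question, a permutation test over shuffled list names gave permutation p = 0.0334 with genes taken as independent, and of 10 splits of the 6 infected arrays, too few for a share under 0.05, the real one had the largest gap between list medians (0.57, highest other 0.45). Relative to genes of like vehicle level the medians of alveolar type 1 (0.05) and fibroblast genes (0.03) were not lowered, so compression may account for these 2 lists. A loss of some cell types, such as ciliated or endothelial cells, and lower expression within them may each contribute and were not separated. Cilia genes did not all move together between the infected groups: ciliated markers fell as a list, but 0 of 10 axonemal dynein heavy chain genes fell and 1 rose. The median of these dynein genes, a family chosen after the data were seen, was 0.06, and -0.10 after cyclic loess. They had already fallen in infection (8 of 10, median -0.52). Against vehicle under anti-LIF 8 were lower and 1 higher (median -0.36). The ciliated list also names the dynein heavy chain genes Dnah5, Dnah9 and Dnah11, so the 2 groups of genes are not separate.

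The 16 genes raised over 2-fold in infection and lower under anti-LIF that did not pass against vehicle there, Hsd11b2 among them, lay -0.56 to 0.91 from vehicle. Of these, 93.8% (interval 69.8 to 99.8) still passed as lower after cyclic loess. Fam20c, named after its values were seen, did not (-0.91 ± 0.29 before and -0.79 after, adjusted p = 0.0508). So far as cyclic loess removes compression of the arrays, this argues against it as the whole cause. The support is limited, since the 16 genes were chosen for being lower in the same arrays and the interval is wide. In simulated data with the observed infection changes and no anti-LIF effect, 0 of 100 draws gave 16 such genes (highest 0). Without any anti-LIF effect hardly a gene can pass in that contrast. This result therefore cannot tell how far selection on high values in the shared infected arrays contributed. An effect of LIF neutralisation remains a hypothesis, and a batch that follows the groups stays open.

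The 6 arrays of a comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3334 infection genes, 9157 anti-LIF genes, 11784 genes for anti-LIF against vehicle and 752 infection genes over 2-fold, in each case with 0 as the highest other, and each was the only 1 of 10 as large. For lists, infection had 27 against 25 (1 of 10) and anti-LIF 18 against 18 (2 of 10). The raised set shifted by 0.60 against 0.48 (1 of 10), and the lowered set by -0.97 against -0.58 (1 of 10).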

How the results depend on the processing

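The cyclic loess runs, the sets chosen on infected minus vehicle lungs alone, the run without both anti-LIF arrays of the highest lower quartile and the filter at the receptor-gene level were chosen after the result was seen. The cause of the differences below was not tested except where fewer genes or arrays were used by construction. The main fit takes 1 spread per gene for all groups, but the anti-LIF arrays were less alike than the others. Their mean correlations with the own group were 0.982 to 0.989, against 0.996 to 0.997 for vehicle and 0.991 to 0.995 for infected arrays. Counts from the main fit depend on this assumption of equal spread. With the brighter 50% of genes, 5185 genes passed under anti-LIF and 6605 against vehicle. With array weights, whose estimation stopped before convergence, 8797 genes passed in infection and 4631 under anti-LIF. In fits of only the 6 arrays compared the counts were 5156 and 6081, and without both anti-LIF arrays of the highest lower quartile 5156 and 6045. The last of these runs kept only 1 anti-LIF array, so its anti-LIF count holds no spread between anti-LIF mice and cannot show robustness. Its infection count equals that of the fit of the 6 arrays compared, because a single array adds nothing to the estimated spread. With an estimated correlation camera called 1 list in infection and 0 under anti-LIF (18 with the preset correlation, 19 with fry), and the shift of the raised set, 0.60, had p = 0.244. Sets with no size threshold shifted by 0.44 and -0.57, and sets chosen on infected minus vehicle lungs alone by 0.35 and -0.38. Leaving out 1 array gave 1835 to 4522 infection genes. A replicate block gave 3027, 8796 and 11531 genes, 759 over 2-fold, 29 and 18 lists and shifts of 0.61 and -0.97. Among named genes a few log2 changes turned sign (the cause was not tested), 1 of them a gene that had passed, Epb42 against vehicle under anti-LIF (0.23, adjusted p = 0.0440). Under anti-LIF, Alas2 had 0.06 with centred arrays, 0.0256 after quantile normalization, 0.23 with array weights and 0.0938 after cyclic loess. After quantile normalization and cyclic loess, Epb42 had -0.0650 and -0.0614, Lep -0.0115 and -0.0561, and Cidea -0.0041 and -0.0246. Against vehicle under anti-LIF, Epb42 turned to -0.0357 and -0.0134 in these settings, which did not pass, and Alas2 0.0121 after cyclic loess. In infection Epb42 had -0.0199 with array weights. Leaving out 1 array gave, in infection, -0.28 to 0.0217 for Hbb-bt, -0.04 to 0.0850 for Epb42 and -0.26 to 0.09 for Alas2, and for Alas2 -0.21 to 0.16 under anti-LIF and -0.23 to 0.0750 for anti-LIF against vehicle. Of the named genes that passed (160, 174 and 175 in the 3 contrasts), 21, 26 and 6 lost their call when 1 array was left out and 9, 49 and 11 in another setting. Of the lists called, 26 of 27 in infection and 12 of 18 under anti-LIF passed in every scaling and without each single array, and no called list turned direction there. Signals near the receptor-gene level limit what dim genes can show: of the named genes that passed, 8, 10 and 14 had 1 of the compared group means below 3.90, and 0, 2 and 1 had both.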

Other observations

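The gene families of this part were chosen after the data were seen, and their tests with them.

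Proteasome subunit genes rose in infection in 19 of 39 (median 0.33, adjusted p = 6.84e-12, and adjusted p = 0.193 with an estimated correlation). Guanylate-binding proteins and immunity-related GTPases, which act against intracellular microbes, rose in 10 of 14 in infection (median 1.02) and in 13 of 14 under anti-LIF (median 0.84, against 0.11 for all genes, adjusted p = 3.85e-05, and adjusted p = 0.440 with an estimated correlation). Axonemal dynein heavy chain genes, the motors of cilia, fell in 8 of 10 in infection (median -0.52, adjusted p = 3.57e-04, and adjusted p = 0.256 with an estimated correlation). Under anti-LIF 0 fell and 1 rose (median 0.06, adjusted p = 0.723), and the median was -0.10 after cyclic loess. Aminoacyl-tRNA synthetase genes rose in 8 of 32 in infection (adjusted p = 0.0019, and adjusted p = 0.256 with an estimated correlation), and under anti-LIF 16 fell and 3 rose (median -0.25, adjusted p = 0.0014, and adjusted p = 0.537 with an estimated correlation).

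Small proline-rich genes of the cornified envelope rose in 10 of 13 under anti-LIF (median 0.47, and 0.22 after cyclic loess, adjusted p = 0.0014, and adjusted p = 0.549 with an estimated correlation). Olfactory receptor genes also passed camera as higher there, with 362 of 1068 up and 0 down (median 0.31, adjusted p = 2.43e-10). After cyclic loess their median was 0.07 (adjusted p = 0.0261). Vomeronasal (adjusted p = 3.09e-04) and bitter taste receptor genes (adjusted p = 0.0028) passed too, but not after cyclic loess. A small adjusted p for a rise under anti-LIF thus does not set a family apart from these. Glutathione S-transferase genes fell in 6 of 19 under anti-LIF (median -0.51, adjusted p = 0.0099, and adjusted p = 0.549 with an estimated correlation), and aldehyde dehydrogenase genes in 11 of 21 (median -0.48, adjusted p = 0.0104, and adjusted p = 0.549 with an estimated correlation). The vehicle arrays differed from each other in Saa3, with a mean of 6.55 ± 1.80 (SD, n = 3) against 10.59 ± 0.04 in infected lungs.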
